A study of Mus musculus with 4 samples.

How the data were processed

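RNA was taken from the posterior part of mouse embryos at E9.5, from intercrosses of heterozygous Jmjd3 mice, and the embryos were staged by time after mating and by the number of somites, per the labels' protocols. The labels give 2 independent RNA samples per genotype. Nothing says that each sample is 1 embryo, so the p-values measure the spread between these samples only. The genotype and number of each sample came from its label. The numbers 1, 9, 3 and 4 are not shared by the genotypes, so nothing pairs the samples.

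The scanner files hold the intensity of each spot in arbitrary units; per the file headers and the submitters' processing notes they were written by Agilent Feature Extraction 10.7.3.1 from a 1-colour scan. The processed intensity is corrected for background and for spatial trends by that software, per the file headers, and is not normalised between arrays. A table of log2 values for the whole series was also deposited, and no label states its scale. Its values matched the log2 processed signal less the 75th percentile of each array and less the mean of the wild-type arrays, with r between 0.995 and 0.997 across probes and 99.9% of probes within 0.01. The column medians were −0.02 and 0.05 for Jmjd3-/- replicates 1 and 9, and 0.02 and −0.02 for wild-type replicates 3 and 4. Scale, centring and direction were found from the values in this way.

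All 4 arrays lay on 1 slide and were scanned together. The Jmjd3-/- arrays were at the ends of the row and the wild-type arrays between them, so the position on the slide and the genotype cannot be told apart. The 75th percentile of the processed intensity was 603 and 578 in Jmjd3-/- replicates 1 and 9 and 599 and 627 in wild-type replicates 3 and 4, and the median local background was 138 to 141. The arrays of a genotype had 0 genes with exactly equal normalised log2 values, with no rounding or tolerance.

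Of 45018 spots, 1639 control spots were left out. The log2 processed signals of the spots of a probe were averaged, which gave 41174 probes, and the 75th percentile of each array was subtracted. The files pair probes with accessions and not with gene names, so names were taken from the RefSeq gene table of the GRCm38.p6 assembly. That table named 26690 probes by accession and 23 by synonym, for 18220 genes, and left 14461 probes without a name. The plan had named probes by a gene name column, which the files do not hold. Coordinates of that table were not used, since the file headers name another build, and it served only for names, chromosomes and gene order. The probe with the highest mean signal over the 4 arrays stood for each gene. A gene was tested if that probe was well above background on both arrays of at least 1 genotype, which left 13581 genes.

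Genotypes were compared with limma 3.58.1 in R 4.3.3 by lmFit and eBayes, with no covariate and Benjamini-Hochberg adjustment over the genes tested. The threshold was an adjusted p under 0.05. A log2 difference is Jmjd3-/- minus wild-type, with the moderated standard error, whose median over genes was 0.105. The prior had 1.79 degrees of freedom. Where a gene was not well above background on either array of a genotype, it is given as "at least N-fold": the mean of the bright genotype against a floor in the dim one. The floor of each array was the lowest signal of any probe well above background, or the gene's own signal where that was higher. The fitted difference of such a gene is no bound. Its p-value belongs to the fitted difference and not to the bound.

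The lists of genes, the rule for naming genes, the tests and most alternatives were fixed before the data were examined. The rule names Kdm6b, the 10 largest differences in each direction among genes past the threshold, and up to 4 members of each list by p, with Hox genes, the sex-linked genes and the genes that flank Kdm6b. Where fewer genes pass, the places are filled with the largest differences at an unadjusted p under 0.05 without overlap of the genotypes. Some genes that the rule names are not reported here. Clone and model names are counted only; 1 of the called genes has such a name, and it is given because so few genes passed. Of the genes named by size, 5 had more than 1 probe above background, and in 1 of these the probes differed in sign.

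The 29 lists cover Hox genes and their paralog groups, tissues of the posterior embryo, cell types that the sample could hold, pathways and technical controls, and 28 had at least 5 tested genes. Each was tested by camera with a preset correlation of 0.01 between genes, by camera with an estimated correlation and by fry, each adjusted over the lists. Camera compares a list with all other genes. Fry tests whether the genes of a list move on balance one way, or in its mixed form in either direction, and compares the list with no other gene. With the preset correlation 11 lists passed, with an estimated correlation 0 and by fry 1. Among the lists that passed, the estimated correlation was highest for the erythroid list (0.885) and the tail bud list (0.748), and near or below the preset value for Hox groups 1 to 4 (−0.042), endothelium (0.008) and hypoxia (0.013). With an estimated correlation camera also uses the residual degrees of freedom of the fit, 2 here, so a call can be lost without a high correlation. Setting members that have only a bound at that bound moved 1 list median, that of the neural list, from −0.76 to −0.66. Some lists share members, such as 4 of the 20 tested gut genes, which other lists also hold. The sex-linked list had 2 tested genes and was not tested.

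The scripts were tested on simulated data for the comparison of Jmjd3-/- with wild-type over 13581 genes. Of genes simulated with a log2 difference of 1, 31.8% were called, of those at 2, 74.6%, and of those at 3, 85.1%. Among 13381 genes without a difference 6 were called. A list moved by 0.5 was called and 0 other lists were. The simulated genes varied independently and with the same spread in both genotypes. The simulation therefore cannot show how often a list of correlated genes is called without a difference.

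The alternatives were normexp background correction with an offset of 50, quantile normalisation, scaling to the median of detected probes, the deposited log2 values, other filters on dim probes, other rules for probes, trend and robust moderation, spots with outlier flags left out, sex-linked genes left out, a rule of 2-fold without overlap, and each array left out in turn. The files hold no mean signal, so normexp used the median signal of each spot in place of the planned mean.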

Results

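Gene expression was measured in the posterior part of E9.5 Jmjd3-/- mouse embryos and of wild-type embryos. Jmjd3, now named Kdm6b, encodes an enzyme that removes repressive methyl marks from histone H3. Total RNA was labelled with Cy3 and hybridised to 1-colour Agilent oligonucleotide arrays, with 1 array per RNA sample and 2 samples per genotype. The samples carry the numbers of their labels, Jmjd3-/- replicates 1 and 9 and wild-type replicates 3 and 4. Between 24631 and 25947 of the 41174 probes, 59.8% to 63.0%, were well above background on an array, and 0 spots were saturated. The number of arrays limits the precision of every value.

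The wild-type arrays were the closest pair, with 157 of 13581 genes more than 2-fold apart and a Pearson r of 0.996 across genes, which are not independent replicates. The Jmjd3-/- arrays were more than 2-fold apart at 431 genes (r = 0.989 across genes). Jmjd3-/- replicate 1 was more than 2-fold from the wild-type arrays at 805 and 705 genes, and Jmjd3-/- replicate 9 at 354 and 332 genes. By this measure replicate 9 was nearer to each wild-type array than to replicate 1.

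The comparison of the genotypes asks which transcripts of the posterior embryo differ between Jmjd3-/- and wild-type. In the Jmjd3-/- samples, genes of the tail bud and presomitic mesoderm were higher, and genes of the neural tube, neurons, neural crest, blood and endothelium were lower, each as a group against all other genes. For blood, the wild-type arrays differed by 0.46 in the erythroid median, more than the genotype difference of −0.36. Over arrays left out, the erythroid median ranged from −0.60 to −0.17 and the macrophage median from −0.73 to −0.20. Anterior Hox genes were higher and the most posterior Hox genes were lower. These group calls were made by camera with a preset correlation between genes and were lost when the correlation was estimated, where the smallest adjusted p of any list was 0.543. By fry, which tests whether the genes of a list move on balance one way, Hox groups 1 to 4 passed (adjusted p = 0.0462), and the other lists that camera called did not (adjusted p from 0.226 to 0.497). In fry's mixed form, which tests for change in either direction, Hox groups 10 to 13, the head list and the hypoxia list each had an adjusted p of 0.0174 and the endothelial list 0.0317. The mixed form did not pass for the tail bud (adjusted p = 0.175), presomitic (0.176), neural (0.105), neural crest (0.340), erythroid (0.370) and macrophage (0.176) lists or for Hox groups 1 to 4 (0.105). Among single genes, 3 were higher and 2 were lower at an adjusted p under 0.05, of 13581 tested (limma).

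Kdm6b itself was represented by 1 probe, A_51_P122017, which was well above background on all 4 arrays. Its normalised log2 signal was 0.35 and 0.11 in Jmjd3-/- replicates 1 and 9, against 2.15 and 2.23 in wild-type replicates 3 and 4. The Jmjd3-/- mean was 25.7% of the wild-type mean, a log2 difference of −1.96 (SE 0.12, n = 2 per genotype), with an adjusted p of 0.149. The gene had rank 10 by p. Whether the probe lies inside the deleted part of the gene is not given in the sources used here, so the lower signal checks the labels only if it does, and a probe outside that part would check nothing. Its processed signal was still 770 and 622 in Jmjd3-/- replicates 1 and 9, above the 75th percentiles of those arrays, 603 and 578. That argues against a probe wholly inside a part deleted on both alleles, unless it also binds other transcripts, which was not tested.

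Hox genes encode transcription factors that pattern the body axis, and the lower paralog numbers act further forward. Of 39 Hox genes, 32 were tested; 19 were higher and 13 were lower in Jmjd3-/-, with a median log2 difference of 0.11. The list as a whole did not pass (camera adjusted p = 0.0916, and adjusted p = 0.556 with an estimated correlation). In paralog groups 1 to 4, 9 of 11 genes were higher, with a median of 0.33 (camera adjusted p = 0.000775). That call was lost with adjusted p = 0.543 with an estimated correlation, while fry gave an adjusted p of 0.0462. Hoxb1 differed by 1.07 (SE 0.25) and Hoxd1 by 1.04 (SE 0.27), whereas the probes of Hoxa4 disagreed, with −0.48 (SE 0.24) for the brighter and 3.81 for the other, so its direction is open.

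In paralog groups 5 to 9, 9 of 14 genes were higher, with a median of 0.27, and the list did not pass (camera adjusted p = 0.0612, and adjusted p = 0.543 with an estimated correlation). It passed without wild-type replicate 4 (median 0.32, camera adjusted p = 0.0279) and with normexp (median 0.19, camera adjusted p = 0.0335), and without Jmjd3-/- replicate 1 its median was 0.09. Hoxa7 differed by 0.73 (SE 0.32), Hoxc9 by 0.71 (SE 0.18) and Hoxb9 by 0.38 (SE 0.10), and Hoxb5 by −0.35 (SE 0.16). In groups 10 to 13, 6 of 7 tested genes were lower, with a median of −0.65 (camera adjusted p = 0.00283, and adjusted p = 0.543 with an estimated correlation). Hoxa11 differed by −0.89 (SE 0.22), Hoxd11 by −0.72 (SE 0.12), Hoxd13 by −0.69 (SE 0.15) and Hoxd10 by −0.65 (SE 0.07). The other tested members, Hoxa10, Hoxa13 and Hoxc10, differed less, with Hoxa13 at −0.16 and Hoxc10 at 0.11. Of the groups 10 to 13, 4 genes passed when adjusted over the list alone and 0 over all genes; over all 32 Hox genes as the list, 1 passed, Hoxd10, and it was lower. Without Jmjd3-/- replicate 9 the median of groups 10 to 13 was −0.53 and the list no longer passed (camera adjusted p = 0.126), and without the filter on dim probes the median was −0.40.

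**Figure D1:**
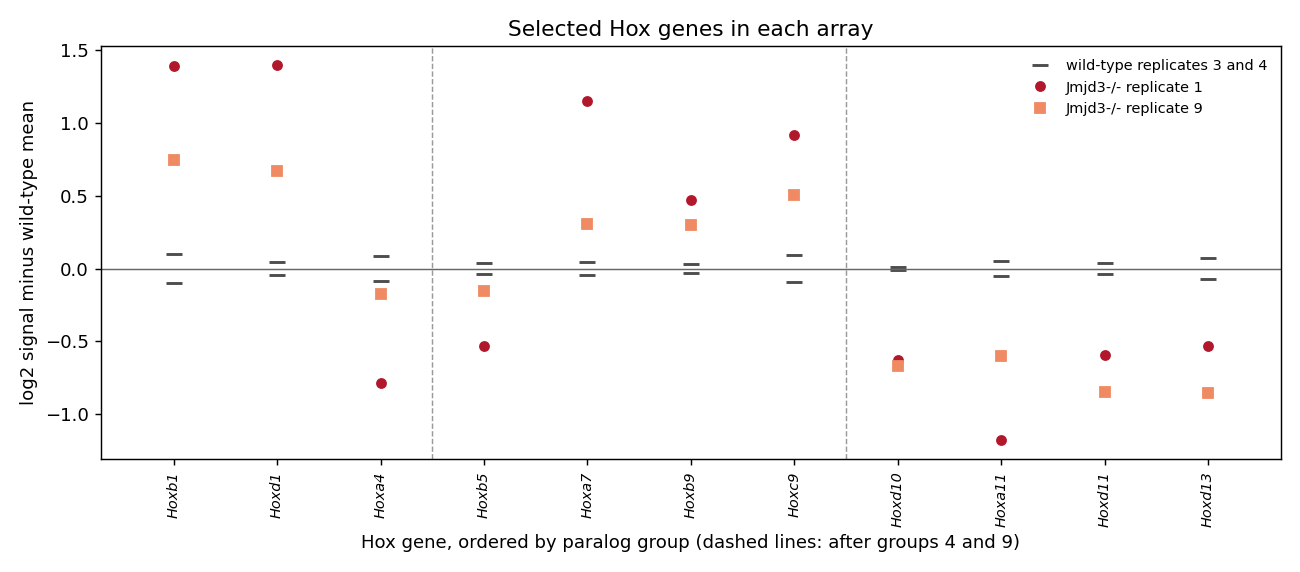
Each column is a Hox gene by its brightest probe, from a selection of the 32 tested, ordered by paralog group. Hoxa10, Hoxa13 and Hoxc10, which differed less than the drawn genes of groups 10 to 13, are not drawn. The vertical axis is the log2 signal of each array minus the mean of the 2 wild-type arrays. Circles and squares are Jmjd3-/- replicates 1 and 9, dashes are the wild-type arrays, and dashed lines part groups 1 to 4, 5 to 9 and 10 to 13; Hoxb1 and Hoxd1 lie above 0 in both Jmjd3-/- arrays, and Hoxa11, Hoxd10, Hoxd11 and Hoxd13 lie below 0 in both.

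Tail bud progenitor genes, which keep the posterior end of the embryo growing, were higher as a group. All 19 tested genes of this list had a positive log2 difference, with a median of 1.09 (camera adjusted p = 1.37e-11, and adjusted p = 0.543 with an estimated correlation). Of these, 12 passed when adjusted over the list alone and 0 over all genes. The caudal homeobox genes Cdx1 and Cdx2 differed by 0.79 (SE 0.11) and 1.45 (SE 0.23), Wnt3a, which encodes a signal that maintains the progenitors, by 1.42 (SE 0.25), and Fgf17 by 1.33 (SE 0.24). The list's median was 1.44 in Jmjd3-/- replicate 1 and 0.68 in replicate 9 against the wild-type mean, and 0.10 between wild-type replicates 4 and 3.

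Genes of the presomitic mesoderm and the segmentation clock, which times the formation of somites, were higher in 21 of 22 cases, with a median of 0.39 (camera adjusted p = 3.39e-06, and adjusted p = 0.543 with an estimated correlation). Adjusted over the list alone 1 gene passed, the Notch feedback gene Nrarp at 0.71 (SE 0.10), and 0 passed over all genes. The Notch ligand genes Dll1 and Dll3 differed by 1.00 (SE 0.22) and 1.30 (SE 0.33), and Tbx6, which specifies presomitic mesoderm, by 1.54 (SE 0.35). Without Jmjd3-/- replicate 1 the median was 0.24, and without replicate 9 it was 0.75.

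The somite, sclerotome and myotome list did not pass: 15 of 22 genes were lower, with a median of −0.13 (camera adjusted p = 0.0916, and adjusted p = 0.543 with an estimated correlation). Adjusted over the list alone, 1 gene passed as higher and 5 as lower, and 0 passed over all genes. The list passed without Jmjd3-/- replicate 1 (median −0.28, camera adjusted p = 0.00215) and without the filter on dim probes (camera adjusted p = 0.0427), and its median was −0.08 without Jmjd3-/- replicate 9 and −0.06 both with a filter on all 4 arrays and without spots marked as outliers. Tbx18 differed by −0.98 (SE 0.12), Pax7 by −0.76 (SE 0.14) and Pax9 by −0.79 (SE 0.15). Lateral plate, limb bud and intermediate mesoderm genes had a median of −0.12 over 21 genes (camera adjusted p = 0.0836), and 4 passed when adjusted over the list alone. These were Prrx1 at −0.74 (SE 0.10), the forelimb gene Tbx5 at −1.05 (SE 0.16), Tbx2 at −0.68 (SE 0.14) and Lhx1 at 1.12 (SE 0.21). The lateral plate median was −0.20 without wild-type replicate 4 and −0.21 without Jmjd3-/- replicate 9, and −0.06 with normexp, and the list passed with chromosome 11 left out, an alternative chosen after the data were seen (median −0.18, camera adjusted p = 0.0462).

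Neural tube and neuron genes were lower in 23 of 26 cases, with a median of −0.76 (camera adjusted p = 0.000136, and adjusted p = 0.596 with an estimated correlation). Adjusted over the list alone, 9 passed as lower and 2 as higher, and 0 passed over all genes. The motor neuron gene Lhx3 was at least 1.51-fold lower and Stmn2, a gene of growing axons, differed by −0.56 (SE 0.12). Hes3, a repressor active in neural progenitors, differed by 0.75 (SE 0.07) and Lhx5 by 1.43 (SE 0.27). Dcx and Tubb3, genes of young neurons chosen after their values were seen, differed by −2.17 (SE 0.50) and −1.34 (SE 0.31), and Dcx was well above background on 1 of 2 Jmjd3-/- arrays. The list's median was −0.25 without Jmjd3-/- replicate 1, −1.24 without replicate 9 and −0.37 with normexp.

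Neural crest genes were lower in 10 of 12 cases, with a median of −0.41 (camera adjusted p = 0.0211, and adjusted p = 0.596 with an estimated correlation), and 0 passed when adjusted over the list alone or over all genes. Ngfr differed by −0.37 (SE 0.12) and Tfap2b by −1.36 (SE 0.50), with −0.35 for its dimmer probe. The median was −0.10 without Jmjd3-/- replicate 1, and without wild-type replicate 3 the list no longer passed (median −0.39, camera adjusted p = 0.0950), nor did it without spots marked as outliers (median −0.37, camera adjusted p = 0.0514). Of 25 head and branchial arch markers 11 were tested, and 9 of these were lower, with a median of −0.49 (camera adjusted p = 0.00355, and adjusted p = 0.556 with an estimated correlation). Barx1 was the 1 gene of that list to pass, over all genes and adjusted over the list alone. Lhx2 differed by −2.57 (SE 0.74), Dlx2 by −0.61 (SE 0.19) and Gbx2 by 0.91 (SE 0.27). The list's median was −0.19 without Jmjd3-/- replicate 1 and −0.79 without replicate 9, and it was −0.32 with normexp and −0.12 without the filter on dim probes.

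Markers of blood and vessels were lower as groups. Primitive erythroid genes were lower in 14 of 15 cases, with a median of −0.36 (camera adjusted p = 0.00355, and adjusted p = 0.596 with an estimated correlation). The embryonic globin genes Hbb-y and Hbb-bh1 differed by −0.88 (SE 0.40) and −0.36 (SE 0.15), and Rhag by −0.81 (SE 0.20). The wild-type arrays differed by 0.46 in the median of this list, and the call was lost without Jmjd3-/- replicate 1 (median −0.17, camera adjusted p = 0.0990) and without wild-type replicate 4 (median −0.17, camera adjusted p = 0.447). The erythroid median was −0.60 without wild-type replicate 3 and −0.56 without Jmjd3-/- replicate 9. Macrophage and blood progenitor genes were lower in 9 of 11 cases, with a median of −0.44 (camera adjusted p = 0.0149, and adjusted p = 0.556 with an estimated correlation). Tyrobp was at least 1.75-fold lower and the platelet factor gene Pf4 differed by −1.77 (SE 0.43). That call was lost without Jmjd3-/- replicate 9 (median −0.33, camera adjusted p = 0.216) and without wild-type replicate 4 (median −0.20, camera adjusted p = 0.122), and with a filter on all 4 arrays (median −0.36, camera adjusted p = 0.0695). Without wild-type replicate 3 the median was −0.73, with normexp it was −0.15, and the wild-type arrays differed by 0.25. Endothelial genes were lower in 16 of 19 cases, with a median of −0.14 (camera adjusted p = 0.00285, and adjusted p = 0.543 with an estimated correlation), and Clec14a and Emcn differed by −0.59 (SE 0.12) and −0.44 (SE 0.10). Without Jmjd3-/- replicate 9 the endothelial list did not pass (median −0.16, camera adjusted p = 0.285), and without Jmjd3-/- replicate 1 its median was −0.22. In these 3 lists 0 genes passed when adjusted over the list alone or over all genes.

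Hypoxia and glycolysis genes were higher in 22 of 26 cases by a small amount, with a median of 0.21 (camera adjusted p = 7.44e-05, and adjusted p = 0.543 with an estimated correlation), and 0 passed when adjusted over the list alone or over all genes. The glucose transporter gene Slc2a3 differed by 0.99 (SE 0.18) and the glycolytic enzyme gene Aldoc by 0.92 (SE 0.19), while Adm, a peptide gene that hypoxia induces, differed by −0.67 (SE 0.13).

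**Figure D2:**
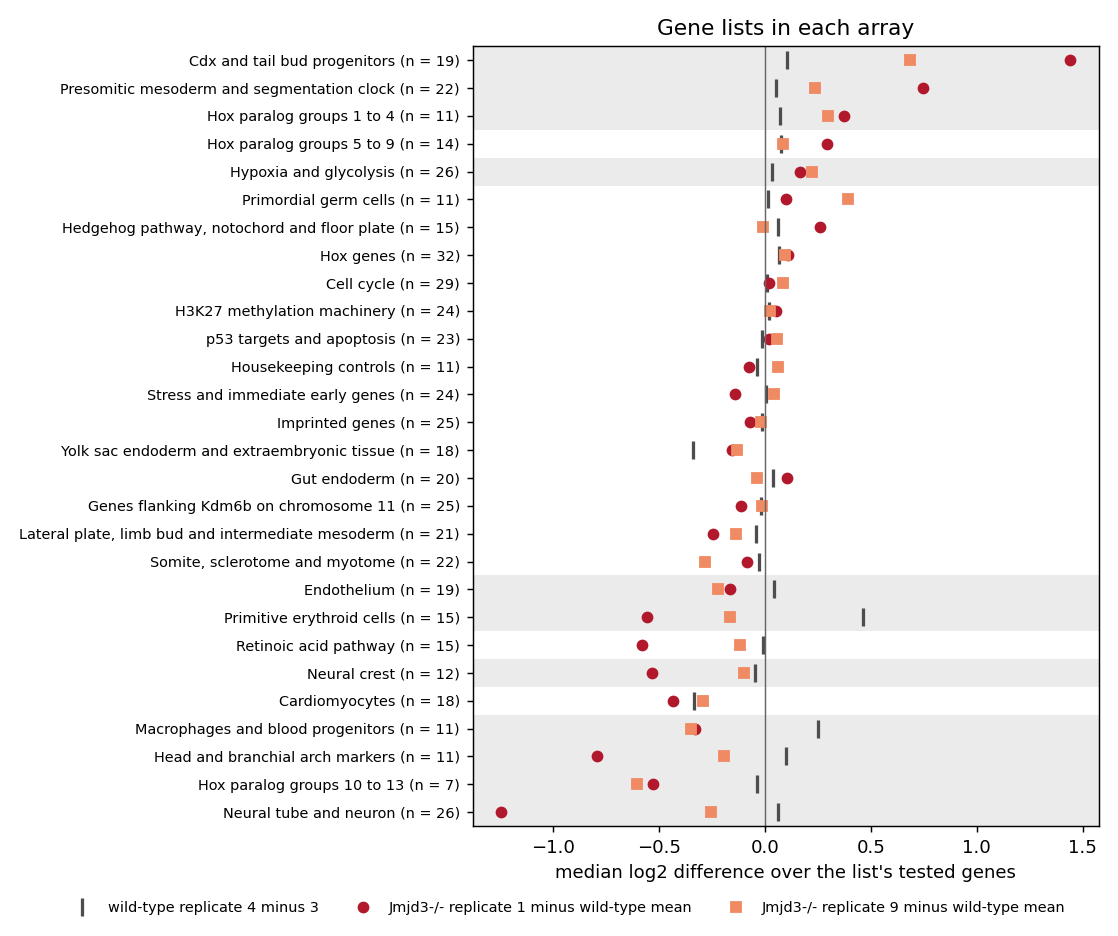
Each row is a gene list with its number of tested genes, and the horizontal axis is the median log2 difference over those genes. Circles and squares are Jmjd3-/- replicates 1 and 9 against the wild-type mean, bars are wild-type replicate 4 minus replicate 3, and shaded rows passed camera with the preset correlation; the tail bud list lies at 1.44 and 0.68 and the neural list at −1.24 and −0.25 in the 2 Jmjd3-/- arrays.

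Cardiomyocyte genes had a median of −0.41 over 18 genes and missed the threshold (camera adjusted p = 0.0503), with Nkx2-5 at −1.86 (SE 0.29) and Myl7 at −1.62 (SE 0.40); 0 passed when adjusted over the list alone. The wild-type arrays differed by −0.33 in that median, and the list passed without wild-type replicate 4 (median −0.78, camera adjusted p = 0.000103) while its median was −0.15 without wild-type replicate 3 (camera adjusted p = 0.254). It also passed with normexp (median −0.17, camera adjusted p = 0.0283) and without spots marked as outliers (median −0.57, camera adjusted p = 0.0149). The camera adjusted p was 0.0440 with median scaling, 0.0177 without the filter on dim probes, 0.0192 with the mean of a gene's probes, and 0.0488 without genes whose arrays lay far apart, an alternative chosen after the data were seen. With a filter on all 4 arrays its median was −0.25 (camera adjusted p = 0.189), and with chromosome 11 left out −0.22 (camera adjusted p = 0.178). Retinoic acid pathway genes had a median of −0.39 over 15 genes (camera adjusted p = 0.0533), with Rarg at 0.46 (SE 0.10) and Rxrg at −0.48 (SE 0.12). That list passed without Jmjd3-/- replicate 9 (median −0.51, camera adjusted p = 0.0354), and its median was −0.12 without Jmjd3-/- replicate 1. Its camera adjusted p was 0.0490 without wild-type replicate 3, 0.0283 with normexp, and 0.0429 both without the filter on dim probes and with a filter on all 4 arrays. The yolk sac and extraembryonic list held members of both signs, with a median of −0.04 (camera adjusted p = 0.554) that was −0.13 without either Jmjd3-/- array, −0.11 without wild-type replicate 4, −0.12 with the mean of a gene's probes, 0.06 without wild-type replicate 3 and 0.007 without the filter on dim probes, and adjusted over the list alone 4 passed as lower and 2 as higher. Among them Afp differed by −1.26 (SE 0.23), Fgb by −2.08 (SE 0.40), Apoa2 by −1.71 (SE 0.35) and Lrp2 by 1.13 (SE 0.24). Gut endoderm genes had a median of −0.04 (camera adjusted p = 0.850) that ranged from −0.08 without the filter on dim probes to 0.11 without Jmjd3-/- replicate 9, and adjusted over the list alone 1 passed as lower, Pyy at −1.09 (SE 0.16), and 1 as higher, Spink1 at 0.85 (SE 0.14).

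The lists for the other cell types and pathways did not pass with the planned processing and had 0 genes past the threshold when adjusted over the list alone. Their medians were 0.16 for primordial germ cells (camera adjusted p = 0.163), 0.04 for the cell cycle (camera adjusted p = 0.124), 0.03 for the enzymes and complexes of the histone mark that Jmjd3 removes (camera adjusted p = 0.505), −0.03 for imprinted genes (camera adjusted p = 0.667) and −0.02 for stress genes (camera adjusted p = 0.721). These medians near 0 moved with single arrays. That of the cell cycle was 0.09 without Jmjd3-/- replicate 1 and 0.02 without replicate 9, that of the histone mark's enzymes 0.05 without Jmjd3-/- replicate 9 and 0.01 without wild-type replicate 4, and that of imprinted genes −0.10 without wild-type replicate 4, −0.07 without Jmjd3-/- replicate 9 and −0.01 without wild-type replicate 3. The stress median was 0.04 without Jmjd3-/- replicate 1, −0.14 without replicate 9, −0.08 without wild-type replicate 4 and −0.06 without wild-type replicate 3. The germ cell median was 0.40 without Jmjd3-/- replicate 1, 0.10 without replicate 9 and 0.01 without wild-type replicate 4, and the list passed without wild-type replicate 3 (median 0.12, camera adjusted p = 0.0300). The Hedgehog and notochord list had a median of 0.13 and a mean of −0.04, which differ in sign (camera adjusted p = 0.356, direction higher); its median was −0.006 without Jmjd3-/- replicate 1, 0.26 without replicate 9, 0.07 without wild-type replicate 3 and −0.02 with the mean of a gene's probes. The p53 and apoptosis list had a median of 0.003 and a mean of −0.04 (camera adjusted p = 0.753, direction higher), and the sign of its median changed with normexp (−0.006), with quantile normalisation (−0.0008), without wild-type replicate 4 (−0.03) and with chromosome 11 left out (−0.02). Housekeeping genes had a median of −0.003 (camera adjusted p = 0.606), which was above 0 without Jmjd3-/- replicate 1 (0.06), without wild-type replicate 3 (0.03), with the mean of a gene's probes (0.03) and with chromosome 11 left out (0.01). The housekeeping median was −0.09 without wild-type replicate 4 and −0.07 without Jmjd3-/- replicate 9. The genes that flank Kdm6b on chromosome 11, in the order of the GRCm38.p6 assembly, had a median of −0.06 (camera adjusted p = 0.124), which was −0.01 without Jmjd3-/- replicate 1 and −0.11 without replicate 9, and the list passed without the filter on dim probes (camera adjusted p = 0.0427). Of 11 probes for 8 genes of the Y chromosome, 0 were well above background on any array. Xist, which is transcribed from the inactive X chromosome, had a normalised log2 signal of 2.92 and 1.82 in Jmjd3-/- replicates 1 and 9 and 2.10 and 2.18 in wild-type replicates 3 and 4. Tsix, transcribed antisense to it, differed by 0.08 (SE 0.20) between the genotypes. With Xist present and no Y signal on all 4 arrays, the values give no sign that sex differed between the genotypes. Whether the Y probes respond in a male sample could not be checked.

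Of the 5 genes past the threshold, Gcg, which encodes the precursor of glucagon, was at least 12.2-fold lower in Jmjd3-/- (adjusted p = 0.0228). It was well above background on both wild-type arrays, at a normalised log2 signal of −1.83 ± 0.27 (SD, n = 2), and not well above background on either Jmjd3-/- array. Its probe was marked as an outlier on at least 1 array, so Gcg was not tested when such spots were left out. Barx1, a homeobox gene of the branchial arches and stomach, was 6.72-fold lower, with a log2 difference of −2.75 (SE 0.10, adjusted p = 0.0409). H2-Bl, a class I histocompatibility gene, was 18.8-fold higher, with a log2 difference of 4.23 (SE 0.12, adjusted p = 0.0228), and its other probes above background gave 4.37 and 2.23. The vomeronasal receptor gene Vmn1r6 was at least 1.52-fold higher (adjusted p = 0.0228). The gene model Gm8267, named after its value was seen, was at least 6.69-fold higher (adjusted p = 0.0228). For Gcg, Vmn1r6 and Gm8267 the adjusted p is that of the fitted difference and not of the bound. It rests on signals that were not well above background in 1 genotype. The SD of those signals was 0.02 for Gcg in Jmjd3-/-, and 0.04 for Vmn1r6 and 0.05 for Gm8267 in wild-type. Members of large families with near-identical copies, here H2-Bl and Vmn1r6, are uncertain, since a probe can bind transcripts of more than 1 copy. With normexp, H2-Bl and Barx1 passed, and Vmn1r6 (adjusted p = 0.454) and Gcg (adjusted p = 0.0779) did not. All 5 passed without Jmjd3-/- replicate 9 and 3 without Jmjd3-/- replicate 1, where Gcg had an adjusted p of 0.0560 and Barx1 of 0.0672. Without wild-type replicate 3 or without wild-type replicate 4, 0 of the 5 passed, and H2-Bl had an adjusted p of 0.134 and 0.126.

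The next largest differences did not pass the adjusted test and are given as values. On the higher side were Cuedc1 and Med1, both genes of chromosome 11. Cuedc1 stood at a log2 difference of 3.40 (SE 0.25), Med1, a subunit of the Mediator complex, at 2.22 (SE 0.16), and S100g, a calcium-binding protein gene, at 2.24 (SE 0.34). Fbxw18 was at least 2.73-fold higher, Cntn6 at least 2.77-fold, Prl2c5 at least 6.79-fold, Cd55b at least 1.71-fold and Olfr1166 at least 1.47-fold. The second probe of Cuedc1 gave 2.53, but the other probes of Med1 gave 0.05 and −0.30. On the lower side, Lhx9, a homeobox gene, stood at −3.84 (SE 1.13), with −5.40 in Jmjd3-/- replicate 1 and −2.29 in replicate 9, and Tbx15 was at least 5.73-fold lower. Several genes for proteins that liver secretes were among the lowest: Itih2 stood at −4.12 (SE 0.41) and was above background on 1 of 2 Jmjd3-/- arrays, Afm was at least 6.69-fold lower and Serpina6 at least 3.68-fold lower. The wild-type arrays themselves spread widely at Itih2 (SD 0.61) and Afm (SD 0.60). Dydc1 was at least 2.69-fold lower (adjusted p = 0.0506), Cstdc1 at least 2.99-fold and the platelet gene Ppbp at least 3.27-fold. The copies of Prl2c5, Cd55b, Olfr1166 and Fbxw18 make these values uncertain as well.

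At an unadjusted p under 0.05 there were 699 genes higher and 805 lower, and the genotypes did not overlap at 46.7% of genes. The mean share over the 3 splits of the arrays into pairs is 33.3%. Genes of an array are not independent, so a split can exceed that mean without a genotype effect, and the share is no test of genotype. With 2 arrays against 2 the smallest p of an exact permutation test is 0.333, and the calls of single genes went to 0 in both directions with quantile normalisation, without the filter on dim probes, with a filter on all 4 arrays or without wild-type replicate 3, and to 0 higher and 1 lower without wild-type replicate 4, against 44 and 5 without Jmjd3-/- replicate 1 and 102 and 119 without Jmjd3-/- replicate 9.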

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

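Leaving out chromosome 11, and leaving out genes whose arrays of 1 genotype lay more than 3 log2 units apart, were chosen after the data were seen; the other alternatives were planned. The counts of 3 higher and 2 lower genes were sensitive. Median scaling, the deposited log2 values and leaving out sex-linked genes gave 3 and 2, with all 5 calls shared. Normexp gave 1 and 1, and trend and robust moderation 1 and 2. Quantile normalisation, no filter on dim probes, a filter on all 4 arrays and testing every probe gave 0 and 0 by limma, with 708, 767, 690 and 1215 higher and 757, 854, 725 and 1206 lower at an unadjusted p under 0.05. Leaving out spots marked as outliers gave 3 and 0, with 696 and 795 unadjusted; Gcg was then not tested and Barx1 had an adjusted p of 0.0501. The mean of a gene's probes, leaving out chromosome 11 and leaving out the genes with arrays far apart each gave 3 and 4. The rule of 2-fold without overlap and without a p gave 109 and 267. The share of higher genes among the calls was 60.0%, and it was 50% with normexp, 33.3% with trend and robust moderation, 42.9% with the mean of probes and 100% without spots marked as outliers. The cause was not tested.

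Leaving out 1 array gave 0 to 102 higher and 0 to 119 lower genes, with the lone array of a genotype assumed to vary like the others. Without Jmjd3-/- replicate 1 there were 44 and 5, without Jmjd3-/- replicate 9 there were 102 and 119, without wild-type replicate 3 there were 0 and 0 (237 and 483 unadjusted), and without wild-type replicate 4 there were 0 and 1 (241 and 502 unadjusted). With a Jmjd3-/- array left out, the spread came from the wild-type pair alone, the closest pair. The Kdm6b difference ranged from −2.08 to −1.84 over arrays left out and passed only without Jmjd3-/- replicate 9 (−1.84, adjusted p = 0.0420); adjusted p lay between 0.0420 and 0.270 over all alternatives. The Hox median ranged from 0.10 to 0.15 over arrays left out, and passed with normexp (0.12, adjusted p = 0.0323) and with the mean of probes (0.26, adjusted p = 0.0158), against an adjusted p up to 0.556 elsewhere. Over the other lists, 429 results kept their direction and side of the threshold, 19 came past it, 30 lost it, 7 changed direction without a call, and 0 reversed. For named genes these were 281, 13 and 28, and 0 reversed. In the list counts, direction is not the sign of the median. Some medians that changed sign count as kept, such as p53 with normexp (−0.006 against 0.003) and Hedgehog with the mean of probes (−0.02 against 0.13). The alternative of array position gave no value, since each genotype holds fixed positions. Genes near background are limited by their signal: Vmn1r6, at least 1.52-fold higher, had an adjusted p of 0.454 with normexp, in a range from 0.0212 to 0.454.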

Other observations

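The tests of the tail share, of replicate 1, of chromosome 11 and of the splits were chosen after the result was seen, as were the patterns. Genes named in this part were chosen after their values were seen. The tests on late-onset and liver genes and on distance along chromosome 11 were set before their values were seen; that on visceral endoderm genes was set after the summary of the list that holds them was known. Beyond the lists, 5301 probes without a gene name were tested, and limma called 0 higher and 0 lower, with 362 and 197 at an unadjusted p under 0.05. A group of 23 genes had arrays of 1 genotype more than 3 log2 units apart. Thumpd1 stood at −7.85 in Jmjd3-/- replicate 1 against 2.19 in replicate 9 and 2.23 and 2.21 in the wild-type arrays, and Foxk2 at 5.49 in Jmjd3-/- replicate 9 against 2.09 in replicate 1.

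Tail bud and presomitic genes were higher and neuronal genes lower in Jmjd3-/-, more so in replicate 1. The rise of the tail bud genes was not confined to replicate 1. In replicate 9 their median was 0.68 above the wild-type mean, and 18 of 19 genes lay above both wild-type arrays. The median absolute difference between the wild-type arrays was 0.11. Replicate 9 is 1 sample and these genes vary together, with an estimated correlation of 0.748, so variation between samples stays possible. A larger share of tail tissue would by itself raise Hox groups 10 to 13, genes used in the tail. Their median was −0.65 (−0.40 without the filter on dim probes), with Hoxa10 at −0.05, Hoxa13 at −0.16 and Hoxc10 at 0.11. That fall does not decide the question, since an effect of Jmjd3 loss on these Hox genes could lower them despite more tail tissue. For these Hox genes, such an effect was not tested apart from a younger stage either. A larger tail share stays open, since the tested head markers (−0.49) and cardiomyocyte genes (−0.41) were lower as medians. A younger stage of the Jmjd3-/- embryos may account for it: 18 of 20 late-onset neuron, muscle and cartilage genes in no fixed list were lower, with a median of −0.39, −0.56 and −0.17 in replicates 1 and 9, and −0.06 between the wild-type arrays. The fixed neural and myotome lists mark the same kinds of cells, and fewer such cells at the same stage would lower these genes too. The late-onset genes therefore do not tell these ideas apart. Staging by somites, per the labels, does not exclude a younger stage, and an effect of Jmjd3 on the pace of differentiation was not tested apart from it.

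Genes of chromosome 11, which carries Kdm6b, were frequent among the 100 smallest p-values other than Kdm6b itself: 21 were on it, 8.43 would be expected, and the odds ratio was 2.92 (95% interval 1.71 to 4.80, Fisher's exact p = 7.40e-05, 2-sided, before allowing for the choice of chromosome). Fisher's test treats genes as independent, which genes of an array are not, so the interval and p overstate the precision. Among these genes of chromosome 11 are Cuedc1 and Med1. Alleles carried along with the targeted locus could give this, but the share of a chromosome's tested genes that were among these 100 was 1.83% on chromosome 11 and 1.61% on chromosome 6, 1.51% on chromosome 14 and 1.43% on chromosome 13, which are not linked to it. A segment centred on Kdm6b would place these genes near it. Their median distance was 277 gene positions on GRCm38.p6, at percentile 43.7 of 10000 random draws. The distance takes no account of the side, so it cannot show a segment that reaches further to 1 side of Kdm6b. The flanking list had a median of −0.06, with −0.01 and −0.11 without Jmjd3-/- replicates 1 and 9. These values leave open both linked alleles in general and a segment centred on Kdm6b.

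Of 6 liver secretory genes that raised the question, all were lower, with a median of −2.32 with the 3 that have only a bound at that bound, and the wild-type arrays differed by −0.85 in the median. Less yolk sac endoderm on the samples is argued against by 4 visceral endoderm genes, Amn, Cubn, Dab2 and Rhox5, of which 0 were lower, with Dab2 at 0.004, and whose median was 0.59, though all 4 are in the fixed lists and used in other tissues, and Afp and Apoa2, used by both liver and yolk sac, were lower at −1.26 and −1.71. Fewer liver bud cells may account for it, but 12 other liver secretory genes had a median of −0.30 (−0.27 with 1 gene at its bound), with 7 lower and 5 higher, from −2.02 for Serpinf2 to 1.10 for Ahsg, which does not decide it. A role of Jmjd3 in the onset of liver genes stays open as untested.

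The 4 arrays form 3 splits into pairs, too few for a share under 0.05. The split by genotype was the 1 split to give as many calls, with 5 genes, and the highest of the others gave 0 (limma, adjusted p). The other splits mix the genotypes within a group, so any difference by genotype or slide position widens their spread and removes calls. Few calls in them were therefore likely in advance, and the comparison decides nothing.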
